A study of Homo sapiens with 4 samples.

How the data were processed

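Total RNA from 4 cultures of established breast cancer cells, 1 per group, was measured on Affymetrix human gene arrays. The deposited values are log2 signals per transcript cluster that the authors made by RMA in Affymetrix Expression Console 1.2, per the submitters' processing notes. RMA corrects background, normalizes quantiles over the arrays and summarises probes. The genome build of the alignment of probes is not given in the sources used here, and no coordinates were used. The deposited gene table supplied the annotation text alone. Its 4 signal columns carry codes that match no sample label and were not used.

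Of 53616 transcript clusters, 22093 carry 1 gene symbol in the deposited annotation, 25 several and 31498 none. Symbols of the first were updated through the RefSeq gene table of the assembly GRCh38.p14, used for names only: 19423 matched by transcript accession, 1251 by symbol and 524 by synonym, and 895 kept the deposited symbol. Clusters with 1 symbol whose mean over the 4 arrays was at or above the median of such clusters (log2 6.76) were used, the brightest cluster standing for each gene. Since the mean over the arrays decides, a gene dim in 1 line or arm can pass. This left 10868 genes, 133 of them with several clusters, and 222 small RNA genes.

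Groups came from the sample labels. Within a line, knockdown minus control is a difference of 2 arrays with no p-value. Across lines, limma 3.58.1 in R 4.3.3 fitted cell line and arm to the 4 arrays with eBayes and Benjamini-Hochberg adjustment, taking an adjusted p under 0.05. This leaves 1 residual degree of freedom beside a prior of 4.42, so the p-values and each SE lean on the spread shared over genes, and the lines stand in for replicates. A gene's interaction cannot be tested beside both terms. Each of 30 gene lists was fixed beforehand, and 27 with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with p adjusted over lists, and also with an estimated correlation. A list's direction is relative to the other genes. Percentiles come from 10000 random lists matched in 20 bins of mean level and describe these arrays only. Counts adjusted over the list alone repeat the adjustment within a list.

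Genes were named by a rule fixed before the data were examined, as were the groups, lists, tests and most alternatives: LASP1 first; per line the 10 largest rises and 10 largest falls; across lines, and between lines, up to 10 called genes in each direction, filled up by the genes with the largest smaller-of-both change, given as values; the 5 genes at each end of the difference in response; and of each list described, the 2 to 4 members with the largest mean change. The names given for counts under alternative settings, and those list members that passed adjusted over the list alone, were chosen after their values were seen. Of the genes this rule picks between the lines, 1 is not reported here.

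The fits were tested on simulated data: 20 sets of 4 arrays of 10868 genes, with 200 changed by knockdown. The fit across both lines recovered 72.5% of genes changed 1.5-fold, 98.2% of those changed 2-fold and 100% of those changed 4-fold. Of its calls 8.42% were false, above the nominal 5%. Calls between the lines were not simulated. Shifting 2 lists by -0.2 gave calls for 100% of them. The simulated noise was independent between genes, with no array-wide shift, and 200 changed genes ease the adjusted threshold. In the data, with 1 gene called, MMP9 at a mean of 1.93-fold did not pass (limma adjusted p = 0.231). The simulated rates therefore do not carry over to the data, and a gene without a call may still have changed 2-fold.

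Alternatives were centring each array on its gene median, cyclic loess, no filter, only the clusters at or above the 0.75 quantile of mean level, clusters with several symbols, a 1.5-fold threshold, limma with a trend or robust prior, an adjusted p of 0.1, dropping a term of the fit, camera with an estimated correlation and Spearman's rho. Values within a gene's posterior SD times the square root of 2, and an r within 0.05, were taken as the same. Leaving out small RNA genes was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.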

Results

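Gene expression was measured in basal-like breast cancer cells with and without knockdown of LASP1, which encodes LIM and SH3 protein 1, an actin-binding protein of focal adhesions. The cells were of the lines MDA-Bone-Un and MDA-MB-231-S, which the series places under MDA-MB-231, an established triple-negative breast cancer line. Each line was studied as a non-silencing control and as a LASP1 knockdown, and all cells were grown for 3 days on growth factor reduced Matrigel, a basement membrane extract, where they formed stellate clusters. Total RNA was hybridised to 4 arrays, 1 per group, so no group has replicates and the number of arrays limits the precision of every value. Comparisons were made over 10868 genes. Within a line a difference is that of 2 single arrays and has no test. Across the lines, the 2 lines served as the replicates (n = 2 per arm).

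The targeted gene was examined first. LASP1 (transcript cluster 16833708) had a log2 signal of 11.37 in the MDA-MB-231-S control and 8.98 in its knockdown, 5.24-fold lower. In MDA-Bone-Un it was 11.36 in the control and 9.10 in the knockdown, 4.79-fold lower. The mean log2 difference of the 2 lines was -2.32 (n = 2 lines, lower in both), with a limma adjusted p of 0.00413. Its SE of 0.08 is limma's, drawn mostly from the spread shared over genes and not from the 2 lines. LASP1 did not differ detectably between the lines (log2 difference 0.05, SE 0.08, adjusted p = 0.710). The call of the knockdown was lost with no filter on mean level (adjusted p = 0.447) and with no term for the cell line (adjusted p = 0.0839), while the fold did not move, and over the other alternatives the adjusted p ranged from 7.77e-07 to 0.00418.

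**Figure D1:**
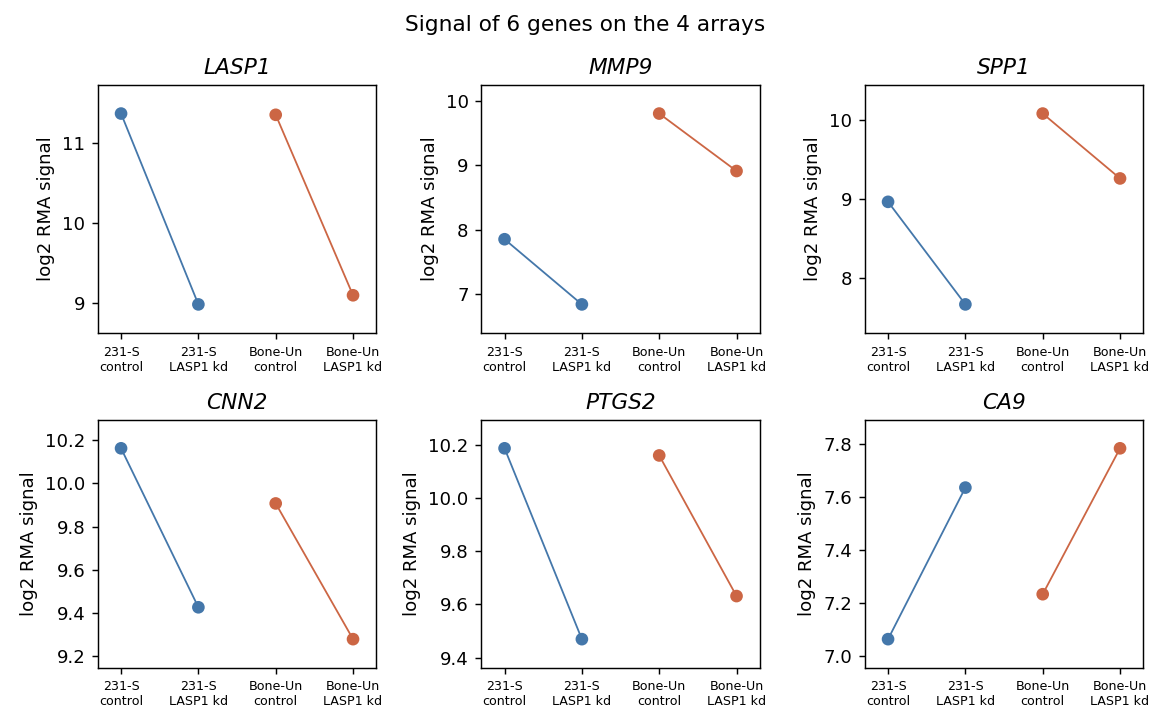
Log2 RMA signal (y axis, scaled separately for each gene) of LASP1, MMP9, SPP1, CNN2, PTGS2 and CA9 on the 4 arrays (x axis). Each point is 1 array, blue for MDA-MB-231-S and orange for MDA-Bone-Un, and a line joins control and knockdown; there are no replicates and so no error bars. LASP1 went from 11.37 to 8.98 and from 11.36 to 9.10.

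In MDA-MB-231-S, the comparison of knockdown with control asked which other genes differed. At least 2-fold lower were 5 genes: LASP1, the urea transporter SLC14A1 (2.59-fold), SPP1, which encodes the secreted phosphoprotein osteopontin (2.46-fold), the glutathione-degrading enzyme gene GGT1 (2.23-fold, with the knockdown signal at 5.71, under the filter's floor) and MMP9, a gelatinase that degrades basement membrane collagen (2.02-fold). The next lowest were the chemokine CCL2 (1.95-fold), PABPC4L (1.86-fold), S100A11 (1.80-fold), the plasminogen activator inhibitor SERPINB2 (1.77-fold) and TRBV23-1 (1.76-fold). At least 2-fold higher was 1 gene, the hyaluronan synthase HAS2 (2.04-fold), followed by MIR505 (1.86-fold), the butyrophilin BTN3A1 (1.77-fold), PIGO (1.74-fold), TLCD2 (1.64-fold), FBXO44 (1.62-fold), ANKRD18A and PGBD4 (both 1.60-fold), ZNF543 (1.59-fold) and ZNF678 (1.58-fold). The knockdown signal of PABPC4L and the control signals of MIR505, BTN3A1, FBXO44 and ZNF678 also lay under that floor. The median difference over all genes was 0.10 on the log2 scale. With each array centred on its gene median, which moved that median to -0.01, no gene was 2-fold higher. At 1.5-fold, 25 genes were higher and 38 lower, and without the filter on mean level 26 were 2-fold higher and 18 lower.

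In MDA-Bone-Un, the same comparison gave 4 genes at least 2-fold lower and 0 at least 2-fold higher. After LASP1, the lowest were TSPYL5 (2.57-fold), the cancer-testis gene SPANXC (2.15-fold), ZNF253 (2.03-fold), the lysosomal enzyme gene IDUA (1.95-fold), MIR185 (1.89-fold), MMP9 (1.86-fold), MTRNR2L2 (1.84-fold), MIR326 (1.78-fold) and PMS2P4 (1.78-fold). The knockdown signals of TSPYL5 (5.85), SPANXC (4.83, control 5.94), ZNF253 (6.59) and IDUA (5.98) lay under the filter's floor of log2 6.76, so each gene 2-fold lower here other than LASP1 rests on a signal under it. The 10 genes with the highest differences included 5 small nucleolar RNAs. SNORA70E (1.89-fold), SNORA11 (1.83-fold), SNORA33 (1.75-fold), SNORA50C (1.69-fold) and SNORA37 (1.66-fold) stood with the histone gene H4C2 (1.87-fold), MIR1224 (1.81-fold), the vault RNA VTRNA2-1 (1.67-fold), ZKSCAN5 (1.65-fold) and CCN3 (1.61-fold). The control signals of SNORA70E, MIR1224, ZKSCAN5 and CCN3 also lay under that floor. The median over all genes was 0.06. At 1.5-fold, 25 genes were higher and 50 lower, and without the filter 17 were 2-fold higher and 22 lower.

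Across both lines, limma called 1 gene lower, LASP1, and 0 genes higher at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1175 genes higher and 174 lower, against 543.4 expected by chance over all genes. This balance turned with arrays centred on the gene median, to 277 higher and 554 lower, and after cyclic loess, to 361 higher and 455 lower. The genes with the lowest values in both lines after LASP1 were not called. MMP9 was 2.02-fold lower in MDA-MB-231-S and 1.86-fold lower in MDA-Bone-Un (mean log2 difference -0.95, SE 0.08, adjusted p = 0.231). SPP1 was 2.46-fold and 1.77-fold lower (mean -1.06, SE 0.13, adjusted p = 0.391). The actin-binding calponin CNN2 was 1.67-fold and 1.55-fold lower (mean -0.68, SE 0.08, adjusted p = 0.391). SPANXC was 1.55-fold and 2.15-fold lower, and PABPC4L had a mean log2 difference of -0.74. ZNF440, ZNF600, KRT8P11 and RP9P had mean log2 differences of -0.70, -0.69, -0.67 and -0.58. The highest values in both lines were of CA9, a hypoxia-induced carbonic anhydrase (mean log2 difference 0.56, SE 0.08, adjusted p = 0.391), the transporter SLCO4A1 (0.55), the growth factor signalling inhibitor SPRY1 (0.56), ZBTB5 (0.56) and ZNF678 (0.60). ZNF680, TIGD2, IFNL3, SNORD10 and SMIM19 had mean log2 differences of 0.44, 0.43, 0.45, 0.51 and 0.44. Of the genes in this paragraph, SPANXC, PABPC4L, ZNF440, ZNF600, KRT8P11, SLCO4A1, ZNF678 and TIGD2 had at least 1 signal under the floor.

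At the 2-fold threshold, 1 gene, LASP1, was lower in both lines and 0 were higher in both. At 1.5-fold, 9 genes were lower in both lines, against 0.175 expected if the lines were independent, and 0 were higher in both, against 0.0575. The 9 include LASP1. In opposite directions at 1.5-fold, 2 genes were lower in MDA-MB-231-S and higher in MDA-Bone-Un, and 0 the reverse. The expected counts treat all genes alike and do not allow for genes that vary more than others. Pairing each control with the knockdown of the other line, the crossed split of the same 4 arrays, gave 9 limma calls against 1 for the knockdown and 245 genes at an unadjusted p under 0.05 against 1349. The contrast of the crossed split is the difference in response between the lines. Each of the 2 fits takes the other's contrast as its residual, so the counts are tied and the crossed split is not a null reference. Its counts were not redone on centred arrays. With only the brightest clusters, those at or above the 0.75 quantile of mean level, 4 genes were lower (LASP1, CNN2, SPP1 and MMP9), and with a trend in limma's prior 7 were. The SD over genes of the mean difference was 0.127 for the knockdown and 0.109 for the crossed split.

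Over the 10868 genes, the knockdown differences of the 2 lines had a Pearson r of 0.158 (Spearman rho 0.135). This correlation is across genes, which are not independent replicates. Without LASP1 it was 0.141. Both differences had the same sign in 62.9% of genes, and in 54.9% once each line's median was subtracted. The correlation was 0.26 among the brightest clusters and 0.0709 without the filter on mean level.

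**Figure D2:**
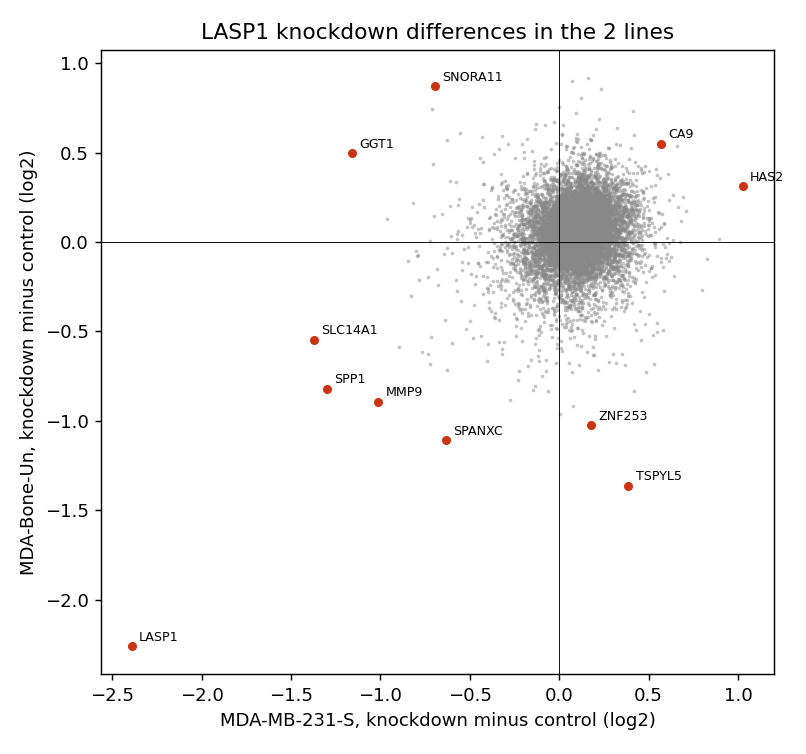
Knockdown minus control on the log2 scale in MDA-MB-231-S (x axis) and in MDA-Bone-Un (y axis); each point is 1 of the 10868 genes, with named genes in red. LASP1 lies alone at the lower left, and MMP9 and SPP1 lie low on both axes.

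Gene groups fixed in advance were compared with all other genes. Of 27 lists with at least 5 measured genes, 5 passed camera with a preset correlation of 0.01: 4 lay below and 1 above the other genes. The p of this test is set against the spread among genes, which are not replicates. It does not measure the spread between arrays or lines. None passed with an estimated correlation (lowest adjusted p = 0.897 with an estimated correlation). That test rests on 1 residual degree of freedom, on which a list could hardly pass, so its lack of calls does not decide for or against a list. Of the 22 measured NF-kappaB and inflammatory targets, 9 were lower in both lines and 1 was higher in both (adjusted p = 1.02e-08, and adjusted p = 0.897 with an estimated correlation). Their median difference was 0.00 in MDA-MB-231-S, at percentile 0.3 of matched random lists, and -0.16 in MDA-Bone-Un, below all 10000 random lists. No member passed over all genes, and 2 passed adjusted over the list alone, the prostaglandin synthase PTGS2 (mean log2 difference -0.62) and the colony-stimulating factor CSF2 (-0.39). IL1B had a mean of -0.43 and IL6 of -0.29, neither past the test.

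The 5 measured chemokines and chemokine receptors, of 22 in the list, lay below other genes (adjusted p = 0.00185, and adjusted p = 0.897 with an estimated correlation). Their median was at percentile 7.5 in MDA-MB-231-S and 0.12 in MDA-Bone-Un, so the list was extreme in the latter line only. Of the 5, 2 were lower in both lines and none passed the test singly. CCL2 had a mean log2 difference of -0.42, made of -0.96 in MDA-MB-231-S and 0.13 in MDA-Bone-Un, and CXCL1 had a mean of -0.19. Of these genes, 3 are also NF-kappaB list members. Of 13 lung metastasis genes, 6 were lower and 3 higher in both lines (adjusted p = 0.00185, and adjusted p = 0.897 with an estimated correlation). The largest mean differences were those of PTGS2 (-0.62) and the collagenase MMP1 (-0.49), and 1 member, PTGS2, passed adjusted over the list alone. This call was lost without the filter on mean level (adjusted p = 0.119). For the 23 matrix proteases and inhibitors the camera adjusted p was 0.0401 (adjusted p = 0.897 with an estimated correlation) with direction down, although 11 members were higher and 7 lower in both lines, the median of the mean differences was 0.04 and their mean -0.05. MMP9, SERPINB2 and MMP1 had the lowest means, -0.95, -0.56 and -0.49, and MMP9 alone passed adjusted over the list alone. This call was lost when arrays were centred (adjusted p = 0.128), after cyclic loess (adjusted p = 0.169) and without the filter (adjusted p = 0.5).

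The 28 hypoxia and glycolysis genes lay above other genes (adjusted p = 0.00725, and adjusted p = 0.897 with an estimated correlation), with 22 higher and 1 lower in both lines. This count alone does not set them apart. The medians of all genes were above 0 as well, 0.10 and 0.06, and the 30 G2/M genes, not called, also had 22 higher and 1 lower. Their medians were 0.17 in MDA-MB-231-S, at percentile 99.6, and 0.11 in MDA-Bone-Un, at percentile 93.6. CA9 (mean log2 difference 0.56) passed adjusted over the list alone, and the hexokinase HK2 (0.37), the collagen prolyl hydroxylase P4HA2 (0.28) and the glycolytic kinase PGK1 (0.24) did not. With only the brightest clusters the list's adjusted p was 0.0507.

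The other 22 lists did not pass, with adjusted p from 0.0807 for osteoblast markers to 0.97 for stem cell associated genes. Among lists nearest to LASP1's known role, the 27 actin cytoskeleton genes had an adjusted p of 0.391, with CNN2 past the test adjusted over the list alone. It was 0.719 for the 28 focal adhesion and LIM protein genes. For the 12 genes of the LASP1 family and its binding partners it was 0.46, and that list includes the knocked-down LASP1 itself. The adjusted p was 0.689 for the G1/S, luminal, epithelial, epigenetic, bone metastasis and interferon lists. It was 0.719 for cholesterol synthesis, mesenchymal markers, TGF-beta targets and ribosomal proteins, and 0.720 for extracellular matrix, basal markers, the unfolded protein response, G2/M and receptor tyrosine kinases. Adjusted over the list alone, SPP1 passed in the bone metastasis and osteoblast lists and DDIT4 (mean log2 difference 0.49) in that of the unfolded protein response. For p53 targets and for YAP and SRF targets it was 0.859. Some lists that did not pass lay far out among matched random lists in 1 line alone. In MDA-MB-231-S, G1/S lay at percentile 0.55 and ribosomal proteins at 0.29, against 47.13 and 92.3 in MDA-Bone-Un. Basal markers lay at 0.64 in MDA-Bone-Un and 92.05 in MDA-MB-231-S. On the upper side, epithelial markers lay at 97.85 in MDA-MB-231-S and 85.23 in MDA-Bone-Un. Leukocyte and endothelial markers, with 4 measured genes each, and fibroblast and mural markers, with 2, were not tested.

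**Figure D3:**
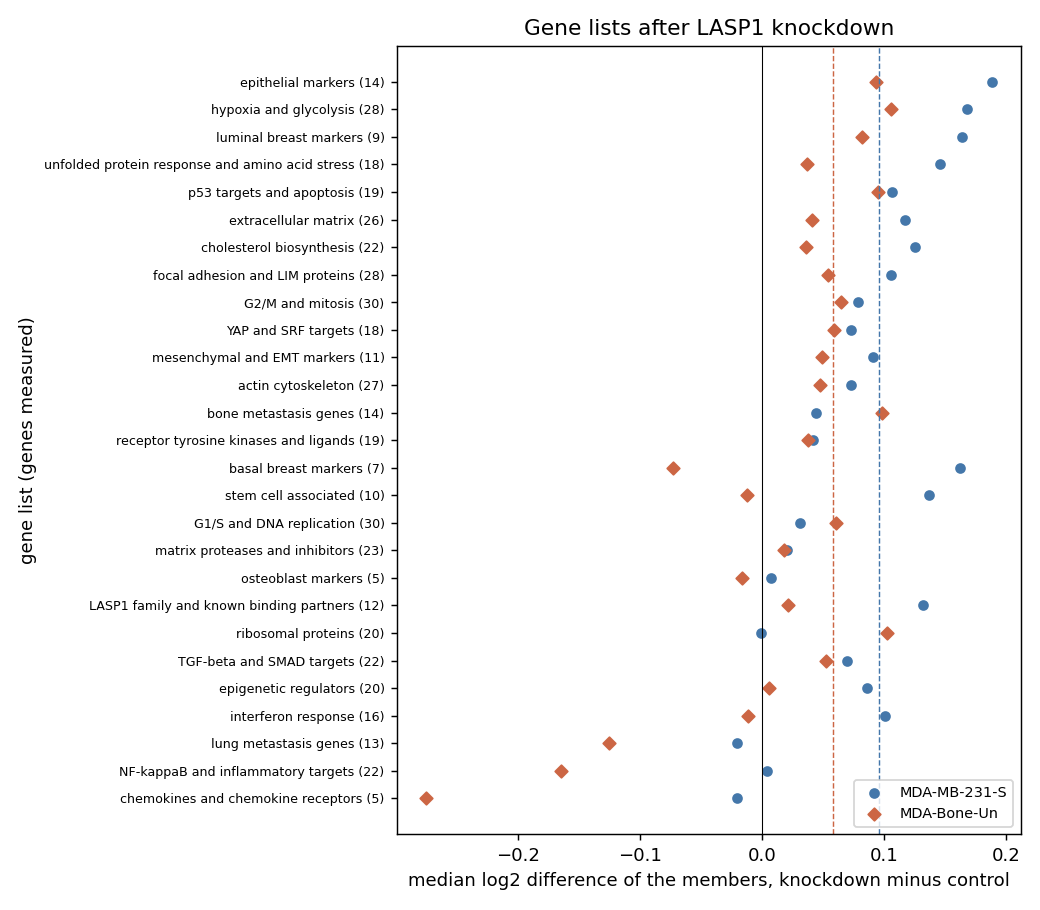
Median log2 difference, knockdown minus control (x axis), of the members of each gene list (y axis, number of measured genes in brackets) in MDA-MB-231-S (blue circles) and MDA-Bone-Un (orange diamonds). Dashed lines mark the medians of all genes, 0.10 and 0.06. The NF-kappaB list lies at 0.00 and -0.16, and the hypoxia list at 0.17 and 0.11.

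The lines were compared with each other in both arms. Limma called 554 genes higher and 1118 lower in MDA-Bone-Un than in MDA-MB-231-S (n = 2 arms per line), of which 40 and 80 differed at least 2-fold. Higher in MDA-Bone-Un were the metallothionein MT1A (5.09-fold, log2 2.35, SE 0.08, adjusted p = 0.0009), the receptor CD96 (4.71-fold), MAGEB2 (4.38-fold), MMP9 (4.03-fold), CGB8 (3.87-fold), the protease inhibitors CST7 (3.57-fold) and SLPI (3.38-fold), FOXR2 (3.55-fold), FKBP10 (3.45-fold) and the adhesion molecule CADM4 (3.13-fold). Lower in MDA-Bone-Un were SPANXC (13.05-fold, log2 -3.71, SE 0.13, adjusted p = 0.0009), SPANXB1 and the cytokine IL1A (both 9.66-fold), the transglutaminase TGM2 (7.84-fold), CAVIN2 (7.76-fold), the collagenase MMP1 (6.51-fold), the integrin ITGB4 (5.51-fold), COL12A1 (5.22-fold) and the desmosome component DSP (5.06-fold). Probes of near-identical family members, such as the SPANX, CGB and metallothionein genes, may not be specific to the gene named. In both MDA-Bone-Un arrays SPANXC, IL1A, TGM2, CAVIN2 and DSP lay under the filter's floor of log2 6.76, as did SPANXB1 in the MDA-Bone-Un knockdown and MT1A, CD96, MAGEB2, FOXR2 and SLPI in the MDA-MB-231-S knockdown, so their folds are those of measured signals, not tested against background.

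With arrays centred on the gene median the calls were 816 higher and 1070 lower, so the share of lower calls was 56.7% in place of 66.9%. Without the filter on mean level 1 gene was higher and 9 lower, and with a trend in the prior 1001 and 1679 were.

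**Figure D4:**
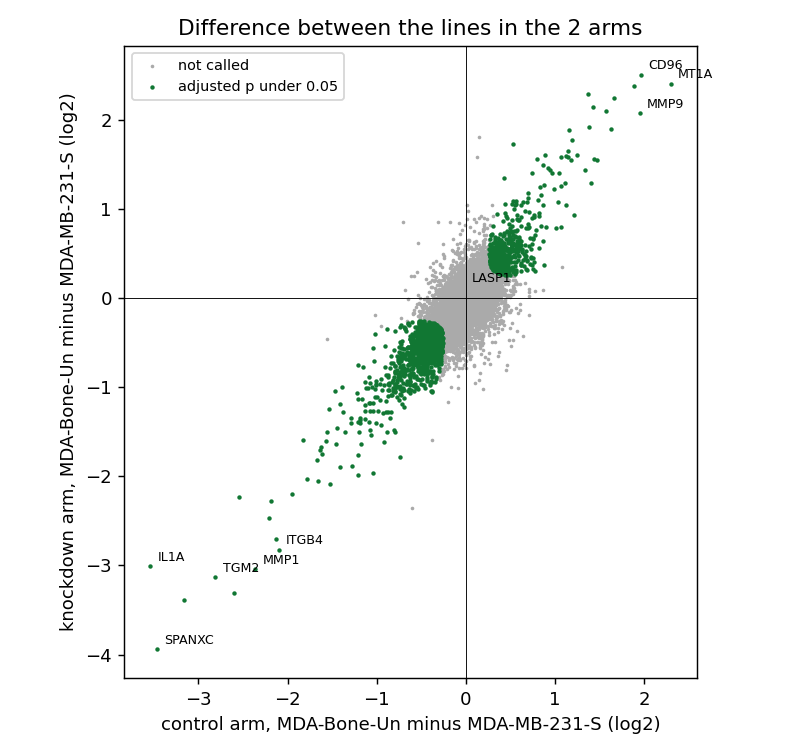
MDA-Bone-Un minus MDA-MB-231-S on the log2 scale in the control arm (x axis) and the knockdown arm (y axis); each point is a gene, green where limma's adjusted p was under 0.05. The differences of the 2 arms had an r of 0.782 across genes; SPANXC and IL1A lie at the lower left and MT1A, CD96 and MMP9 at the upper right.

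Between the lines, 6 lists passed camera with the preset correlation and none with an estimated one (lowest adjusted p = 0.692 with an estimated correlation). The latter again rests on 1 residual degree of freedom and decides nothing. Of 16 interferon response genes, 11 were lower in MDA-Bone-Un, 0 higher and 5 not called (adjusted p = 0.000576, and adjusted p = 0.692 with an estimated correlation), with 11 lower adjusted over the list alone, among them the RNA sensor RIGI (2.41-fold), SAMD9 (1.98-fold) and DDX60 (1.88-fold). Of 22 NF-kappaB targets, 9 were lower and 13 not called (adjusted p = 0.00418, and adjusted p = 0.692 with an estimated correlation), with IL1A 9.66-fold, TNFAIP3 2.14-fold and ICAM1 1.66-fold lower. Adjusted over the list alone, 13 were lower and 2 higher, and the list's call was lost with only the brightest clusters (adjusted p = 0.183). Of 5 chemokines and receptors, 4 were lower (adjusted p = 0.00418, and adjusted p = 0.692 with an estimated correlation), CXCR4 by 2.26-fold and CXCL8 by 1.53-fold, and CCL2 was 2.01-fold lower in value without passing. All 5 were lower adjusted over the list alone, and without the filter the list's direction turned (adjusted p = 0.928). Of 22 cholesterol synthesis genes 3 were lower (adjusted p = 0.025, and adjusted p = 0.692 with an estimated correlation), including LSS (1.38-fold) and ACAT2 (1.29-fold), and 4 adjusted over the list alone. Of 7 basal markers 2 were lower, ITGB4 (5.51-fold) and EGFR (1.49-fold), with an adjusted p of 0.0413 for the list (adjusted p = 0.692 with an estimated correlation). Adjusted over the list alone 3 were lower, and the call was lost without the filter (adjusted p = 0.141). The 30 G1/S and DNA replication genes lay higher in MDA-Bone-Un (adjusted p = 0.00204, and adjusted p = 0.692 with an estimated correlation), with a median of 0.16 in controls and 0.17 in knockdowns, although 1 member, POLE2 (1.41-fold), was called singly, over all genes and over the list alone.

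The other 21 lists did not pass between the lines. Under some alternatives G2/M, p53 targets, epithelial markers, focal adhesion and stem cell associated genes passed. Of 23 matrix proteases and inhibitors 8 were lower and 3 higher (adjusted p = 0.149), with MMP1 (6.51-fold) and the plasminogen activator PLAT (3.21-fold) lower and MMP9 (4.03-fold) higher. Of 14 bone metastasis genes 7 were lower and 1 higher (adjusted p = 0.12), MMP1 lower and SPP1 2.56-fold higher. The adjusted p was 0.0552 for G2/M and 0.0579 for ribosomal proteins. It was 0.12 for p53 targets, epithelial markers, osteoblast markers, stem cell associated genes and focal adhesion genes, 0.132 for TGF-beta targets and 0.315 for YAP and SRF targets. It was 0.443 for extracellular matrix and luminal markers, 0.455 for receptor tyrosine kinases, 0.501 for the unfolded protein response and 0.605 for mesenchymal markers. It was 0.871 for the LASP1 family and for epigenetic regulators, 0.957 for the lung metastasis and hypoxia lists, and 0.99 for the actin cytoskeleton.

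Whether the lines responded differently to the knockdown was given as values, since the 4 arrays leave no degree of freedom to test it beside cell line and arm. The crossed split has the same contrast, but its 9 calls take the knockdown effect itself as residual spread. The difference between the responses was at least 2-fold for 21 genes and at least 1.5-fold for 217. It was most positive, a higher response in MDA-Bone-Un, for GGT1 (1.65 on the log2 scale), SNORA11 (1.56), VTRNA2-1 (1.457), the secreted serpin SERPINF1 (1.198) and the histone gene H3C7 (1.16). It was most negative for TSPYL5 (-1.75), MIR326 (-1.25), EOLA2 (-1.22), the cathepsin CTSO (-1.21) and ZNF253 (-1.20). GGT1, VTRNA2-1, SERPINF1, H3C7, TSPYL5, CTSO and ZNF253 had at least 1 signal under the floor. Without the filter 218 genes differed at least 2-fold, and among the brightest clusters 1 did.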

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

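The tests of the small RNA, histone and G1/S genes were chosen after the results were seen.

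Among the genes the naming rule picked, 16 moved in opposite directions in the 2 lines, each by more than 0.118 on the log2 scale; these differences were not tested, since each is made of 4 single arrays. Response in MDA-Bone-Un minus response in MDA-MB-231-S was 1.65 for GGT1, 1.56 for SNORA11, 1.457 for VTRNA2-1, 1.198 for SERPINF1, 1.16 for H3C7, 1.09 for CCL2, 1.04 for TRBV23-1, 0.91 for FOXR2, 0.54 for CADM4 and 0.53 for IL1A. It was -1.07 for PIGO, -1.20 for ZNF253, -1.21 for CTSO, -1.22 for EOLA2, -1.25 for MIR326 and -1.75 for TSPYL5. CCL2 was 1.95-fold lower in MDA-MB-231-S and 1.09-fold higher in MDA-Bone-Un.

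Clusters without a gene symbol are outside the comparisons of the report. Of 6309 at or above the floor, 2 were at least 2-fold higher after knockdown in both lines and 9 at least 2-fold lower in both. For the latter 1.19 were expected if the lines were independent, and 3 moved at least 2-fold in opposite directions. This set varied more than the genes with a symbol. At least 2-fold higher were 24 and lower 119 in MDA-MB-231-S, and 29 and 63 in MDA-Bone-Un. The expected count does not allow for clusters that vary more than others. Among clusters at least 1.5-fold lower in both lines, the largest falls were -6.26 in MDA-MB-231-S and -4.27 in MDA-Bone-Un, beyond those of LASP1.

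The 222 small RNA genes had a median difference of 0.11 after knockdown in MDA-Bone-Un, at percentile 100 of matched random lists, and lay at percentile 0.02 in MDA-MB-231-S. In MDA-Bone-Un the 97 snoRNA genes had a median of 0.17, at percentile 100, the 105 miRNA genes a median of 0.02, at percentile 7.04, and of the whole set 10 were at least 1.5-fold higher and 7 at least 1.5-fold lower. Noise of clusters with few probes stays open, since the set was picked from these differences, the random lists are matched on mean level alone, and its SD was 0.31 against 0.17 for all genes. A different yield of RNA without poly-A tails and more cells in S phase were also looked at. The replication-dependent histone genes, chosen after their values were seen, lay at percentile 97.55 in MDA-Bone-Un. That value is within resampling error of a bound whose allowance was set afterwards, so it does not decide. In MDA-MB-231-S the histone genes lay at percentile 1 and the G1/S list at 0.55, both low like the small RNA genes there. In MDA-Bone-Un the G1/S list lay at percentile 47.13, which the written bound took as speaking against S phase. Its median of 0.06 lay below that of the small RNA genes by less than its members' SD of 0.11, with members going both ways, so S phase is not excluded. An effect of the knockdown in this line was not tested.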

How the results depend on the processing

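Leaving out small RNA genes was chosen after seeing the data. The alternative that used the second deposited value table was not run, since its columns match no sample label. Each knockdown was paired with the control of its line through the cell line term, and a block on replicate number could not be fitted with 1 sample per group. LASP1's difference in each line kept its direction and its size, within the spread of a gene, under centring and cyclic loess. Array signal over background limits dim genes, and the filter on the mean over the arrays kept genes that are dim in 1 line or arm, such as SPANXC, IL1A and GGT1. The cause of the changes below was not tested, except that no filter and the brightest clusters change which genes are tested and the spread shared over them, and a lower threshold takes in more genes.

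Centring and cyclic loess both gave 0 genes at least 2-fold higher in MDA-MB-231-S. Without the filter, 26 genes were 2-fold higher and 18 lower in MDA-MB-231-S, 17 higher and 22 lower in MDA-Bone-Un, 0 genes were lower across both lines, r was 0.0709, 1 gene was higher and 9 lower between the lines, 218 differed in response, and 3 lists moved after knockdown. In the brightest clusters, 0 genes were 2-fold higher and 3 lower in MDA-MB-231-S, 1 was lower in MDA-Bone-Un, 4 were lower across both lines, r was 0.26, 1 gene differed in response, and 3 lists moved after knockdown. At 1.5-fold, 25 genes were higher and 38 lower in MDA-MB-231-S, 25 higher and 50 lower in MDA-Bone-Un, 9 lower in both, and 217 differed in response. With a trend, 7 genes were lower after knockdown, and 1001 were higher and 1679 lower between the lines. At an adjusted p of 0.1, 1077 were higher and 1834 lower between the lines. With no cell line block 0 genes were lower after knockdown. An estimated correlation, on 1 residual degree of freedom, called 0 lists after knockdown and 0 between the lines.

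Lists changed direction without passing, under the no-filter setting, after knockdown for extracellular matrix (adjusted p 0.797), YAP and SRF targets (0.833), receptor tyrosine kinases (0.719) and ribosomal proteins (0.954), and between lines for chemokines (0.928, a call that was lost) and lung metastasis genes (0.675). In the brightest clusters they did so after knockdown for mesenchymal markers (0.959), p53 targets (0.869) and stem cell associated genes (0.766), and between lines for mesenchymal markers (0.761), hypoxia (0.183) and lung metastasis genes (0.807). Centring turned the actin cytoskeleton (0.977) and loess hypoxia (0.968) between the lines. Of the named genes' mean differences after knockdown, 118 values under the alternatives of scaling, filter, cluster choice and limma's prior kept their direction and side of the threshold, 6 passed it and 1, LASP1 without the filter, no longer did. The fit with no cell line block is outside this tally, and LASP1 did not pass there either (adjusted p 0.0839). Between the lines 112 kept it and 16 no longer passed, all without the filter.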

Other observations

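The tests of the crossed split and of genes below the floor were chosen after the result was seen.

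Gene families outside the fixed lists were looked at as values, by families chosen after the data were seen. Of 97 snoRNA genes, 11 were called higher and 3 lower in MDA-Bone-Un than in MDA-MB-231-S, by limma's adjusted p, while of 105 miRNA genes 2 were higher and 7 lower. Of 7 MAGE genes 1 was higher and 2 were lower, and both measured SPANX genes were lower. Of 5 metallothioneins 2 were higher. Of 267 ZNF zinc finger genes 9 were higher and 21 lower. Over all 10868 genes 554 were higher and 1118 lower, so an excess of lower calls is not particular to the ZNF or miRNA genes. These family counts were not recomputed under other scalings.

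The NF-kappaB targets lay below other genes after knockdown by camera with the preset correlation, whose p measures spread among genes and not between arrays. A level-dependent bias between arrays is argued against, since the list kept its direction after cyclic loess with an adjusted p of 1.53e-06. Members shared with the chemokine and lung metastasis lists are not the whole cause, since the 18 members in neither list gave a camera p of 1.1e-06, also downward. Variation between single arrays stays open. The crossed split called 0 lists against 5, but it is a single other split whose residual is the knockdown contrast, so it is not a null reference. Camera with an estimated correlation gave an adjusted p of 0.897, but on 1 residual degree of freedom a list could hardly pass, so this value decides nothing. Of the 22 members 9 were lower in both lines, and an effect of LASP1 loss on these genes was not tested apart from this.

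At an unadjusted p under 0.05, 87.1% of the genes were higher after knockdown. After centring each array on its gene median the share was 33.3%, and after cyclic loess 44.2%. The bound written beforehand took a share below 40% as speaking against an array-wide shift; that bound was wrong, because a share below 40% also ends the excess of higher genes, and both corrections set the gene median near 0 by construction, so neither value decides whether the shift is technical. The bound for loess, met at 44.2%, was set aside for the same reason, and both readings were settled after the values were seen. The 10546 genes below the floor had a median difference of 0.07 in MDA-MB-231-S and 0.007 in MDA-Bone-Un, so the smaller ratio to the tested genes was 0.128, which leaves open a shift that also reaches genes below the floor. A small rise in these data therefore cannot be told apart from an array-wide shift, since the medians of the tested genes were above 0 in both lines. Small falls go against a shift in that direction, and their cause was not tested.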
